A study of Mus musculus with 3 samples.

How the data were processed

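The series profiled where the transcription factor STAT5A was bound in the genome of mouse CD8 T cells by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA crosslinked to a protein is recovered with an antibody and sequenced. Per the labels, the cells carried the TCRP1A receptor, which recognises the P1A tumour antigen. They were stimulated with that antigen and received an active form of STAT5 (STAT5CA) after 24 h. They were cultured for a further 48 h, transferred into congenic hosts and recovered as memory cells from spleen and lymph nodes 70 days later. The 3 libraries were 2 immunoprecipitations with an antibody against STAT5A and 1 input of sonicated chromatin without antibody. The input had no peak list among the files analysed here, so no value below was compared with a background library. Numbers 1 and 2 of the ChIP libraries only name them. The labels call the second library a replicate, and nothing in them says whether the libraries came from separate animals or cultures, so the spread between them may be technical.

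The deposited files hold 1 peak list for each ChIP library, with chromosome, start, end and a score for each peak. Peaks were called separately for each library. The submitters' processing notes name HOMER and the mouse build mm9, without a version or a role, and the threshold, control and filters of peak calling are not given in the sources used here. The name of the library 1 file carries a short suffix that the library 2 file lacks and that no source explains. Whether regions were filtered from library 1 alone is therefore not known, which bears on peaks found in library 2 only. The score of each peak is the authors' own value, deposited as a whole number with no stated scale. In the comparisons it ranked or grouped peaks within a list and was correlated across shared peaks, and the closing section also sets its ratio between the libraries on X against that on autosomes. The files give no read totals, so the sequencing depth is unknown. Positions below are on mm9, counted from 1.

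Peaks were compared with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. The overlap expected by chance came from 1000 circular shifts of the library 2 list within each chromosome, which keep the widths and spacing of the peaks. The one-sided p-value was the share of shifts with as much overlap, and 0.001 is the smallest that 1000 shifts can give. Clusters were runs of at least 3 shared peaks with neighbouring centres within 20 kb, and their chance number came from 1000 random redraws of the positions of shared peaks within each chromosome. Shares of peaks carry 95% Wilson intervals, which cover counting error only. Shares between chromosomes were compared with two-sided Fisher's exact tests or a chi-square test, and the odds ratio at matched score with the Mantel-Haenszel method in statsmodels 0.14.6. Score correlations across shared peaks have p-values from 100000 permutations. These tests compare 2 libraries peak by peak, and peaks are not biological replicates. The overlap and cluster functions were tested on simulated data. A simulated list with 49.7% of library 1 peaks planted was recovered at 49.7%, and all 40 planted clusters were found.

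The tests of peak position relative to genes, of 12 sequence motifs, and of 11 gene lists fixed before the data were examined were not run, because no mm9 sequence or annotation was used here and coordinates were not converted between builds. Peaks are therefore given by position without a gene name. For the same reason the genes that were to be named by rule are not reported. The rule also named the 10 shared peaks with the highest mean percentile of score in both lists and the 3 clusters with the most shared peaks, and these are reported. Ties between clusters, which the rule did not cover, went to the shortest cluster. Planned deciles of score were replaced by classes of score, set after the scores were seen, because the scores take few distinct values. Numbers of protein-coding genes per chromosome were taken from the RefSeq annotation of GRCm38.p6 without using its coordinates. Alternatives covered the overlap rule, a stricter score threshold, equal list lengths, autosomes alone, a local chance model, the distance that joins a cluster and each library alone.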

Results

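STAT5A ChIP-seq peak lists were compared between 2 libraries of memory CD8 T cells that carried active STAT5, recovered 70 days after transfer. STAT5A is a transcription factor activated downstream of receptors for cytokines such as IL-2. The list of library 1 held 14627 peaks, of which 14625 were 205 bp wide, with a median score of 27 and a range of 19 to 179. The list of library 2 held 19236 peaks, all 189 bp wide, with a median score of 11 and a range of 8 to 267. The peaks covered 2998 kb in library 1 and 3636 kb in library 2. The study concerned the effector program that active STAT5 sets in CD8 T cells. The samples used here hold no cells without active STAT5, and no peak list of the input was analysed, so the comparison that the design allowed was between the 2 ChIP libraries: which sites were found in both, and where the lists differed.

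STAT5A peaks were found at 7877 sites in both libraries. These sites made up 53.9% of library 1 peaks (95% interval 53.0 to 54.7%) and 40.9% of library 2 peaks (40.3 to 41.6%). Circular shifts of the library 2 list gave a mean of 44.8 shared peaks, so the observed number was 176 times the chance number (permutation test by shifting, one-sided p = 0.001, the smallest that the shifts could give). The shifts place peaks anywhere along a chromosome, so the excess does not tell STAT5A binding from background common to both libraries. That multiple depended on the settings, from 50.5 when peaks within 500 bp counted as shared to 352 when peaks had to overlap by 50% of both widths. The paired peaks lay close together, with a median distance of 27 bp between their centres, and 77.9% of the pairs lay within 50 bp. The overlap rule itself limits this distance. Requiring centres within 100 bp kept 7689 of the 7877 sites, while the chance mean fell from 44.8 to 23.0. A further 6750 peaks of library 1 and 11359 peaks of library 2 were found in 1 library only.

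The 10 shared sites with the highest mean percentile of score over both libraries lay on 6 chromosomes. The site with the highest mean rank lay on chromosome 9 at 17030702 to 17030906, where the score was 95 in library 1 and 26 in library 2. The next was on chromosome 14 at 54623133 to 54623337, with scores of 75 and 26. Chromosome 17 held sites at 4626377 to 4626581, with scores of 63 and 34, and at 53090343 to 53090547, with scores of 67 and 24. Chromosome 5 held sites at 151522697 to 151522901, with scores of 63 and 25, and at 52543758 to 52543962, with scores of 63 and 23. On chromosome 6 the site at 35607012 to 35607216 had scores of 63 and 25. Chromosome 1 held sites at 168112795 to 168112999, with scores of 75 and 23, and at 97348414 to 97348618, with scores of 55 and 47. The remaining site, on chromosome 9 at 72309393 to 72309597, had scores of 59 and 26. Positions are those of the library 1 peak, and scores are given for library 1 and then library 2. The annotation of these sites was not analysed here. The scale of the scores is not stated, so the levels of the 2 lists cannot be set against each other.

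Sites with higher scores were mostly found in both libraries more often, up to scores of 43 to 47 in library 1 and 20 to 27 in library 2. In library 1 the shared fraction was 44.3% of the 4180 peaks with scores of 19 to 23 (42.8 to 45.8%) and 65.7% of the 1256 peaks with scores of 43 to 47 (63.0 to 68.3%). In library 2 it was 26.9% of the 1952 peaks with scores of 8 to 9 (25.0 to 29.0%) and 62.9% of the 668 peaks with scores of 20 to 27 (59.1 to 66.5%). Above these classes the fraction was lower, at first with overlapping intervals. In library 1 it was 63.8% at scores of 51 to 59 (59.7 to 67.6%) and 58.8% at 63 to 75 (49.1 to 67.9%). In library 2 it was 45.8% of the 48 peaks with scores of 28 to 35 (32.6 to 59.7%). The highest classes had the lowest fractions. In library 1, 12 of 44 peaks with scores of 79 or more were shared, which is 27.3% (16.3 to 41.8%), and 6 of 76 library 2 peaks with scores of 36 or more, which is 7.89% (3.67 to 16.2%). The median score of shared peaks was 31 in library 1, against 27 for peaks of that library alone, and 12 in library 2, against 11. Scores rose in steps of just under 4.00 in library 1 and of 1.16 in library 2, so both differences were about the smallest that the scores allow. Standard deviations were 9.20 for shared and 9.90 for single-library peaks in library 1, and 3.66 and 7.48 in library 2. Across the 7877 shared pairs the scores of the 2 libraries were weakly related, with Spearman's rho of 0.08 and Pearson's r of 0.11 (permutation p = 1e-05 for rho, the smallest that the permutations could give). This correlation is across peaks, which are not independent replicates. It covers only sites that passed the thresholds of both libraries, so it does not measure how well binding strength repeats over all sites.

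**Figure D1:**
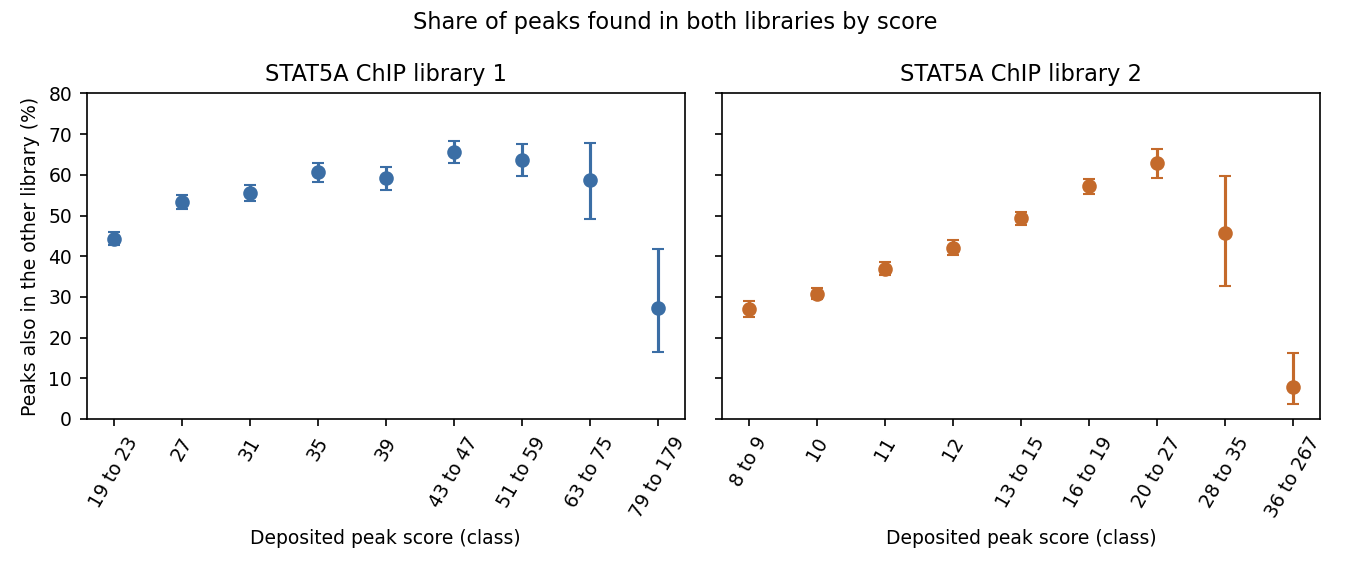
Percentage of peaks of each library that overlapped a peak of the other library (y axis) in classes of the deposited peak score (x axis). Points are shares and bars are 95% Wilson intervals. The share rose to 65.7% in library 1 and 62.9% in library 2 and was 27.3% and 7.89% in the classes with the highest scores.

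The X chromosome separated the libraries. It held 537 peaks in library 1, 3.67% of the list, and 294 peaks in library 2, 1.53% of the list. The X share was 2.40 times as high in library 1 (95% interval 2.09 to 2.76, Fisher's exact test, two-sided p = 3.3e-36). The corresponding ratios of the 19 autosomes lay between 0.88 on chromosome 5 and 1.15 on chromosome 18. X peaks of library 1 were found in library 2 in 131 of 537 cases, which is 24.4% (21.0 to 28.2%). Autosomal peaks were found in 55.0% (54.2 to 55.8%), with a range of 51.2 to 58.8% over single autosomes (Fisher's exact test of X against autosomes, two-sided p = 2.2e-45). In the other direction 44.6% of library 2 X peaks were found in library 1 (39.0 to 50.3%). Relative to the median autosome, the density of peaks on X was 0.576 times as high in library 1 and 0.237 times as high in library 2.

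The Y chromosome went the other way, with 3 peaks in library 1 and 39 in library 2 (Fisher's exact test, two-sided p = 3.7e-07). The library 1 peaks lay between 2765700 and 2772887, and those of library 2 between 324347 and 2883737. Of the 39 peaks of library 2, 26 lay within 5 kb of another, so the test, which counts each peak as independent, gives too small a p. The lists shared 1 Y site. X and Y were the 2 chromosomes whose share differed by more than 1.5 times, leaving out the mitochondrial genome, which held 1 peak in library 2 and 0 in library 1. The planned chi-square test over the autosomes, X and Y gave 236 with 20 degrees of freedom (p = 6.8e-39). Shares also differed among the autosomes alone by a smaller amount (chi-square of 55.4 with 18 degrees of freedom, p = 1.1e-05). With only peaks above the median score of each list, the autosomal difference did not pass the threshold (chi-square test, p = 0.074), with ratios of 0.84 to 1.12 among 7227 and 9389 peaks.

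**Figure D2:**
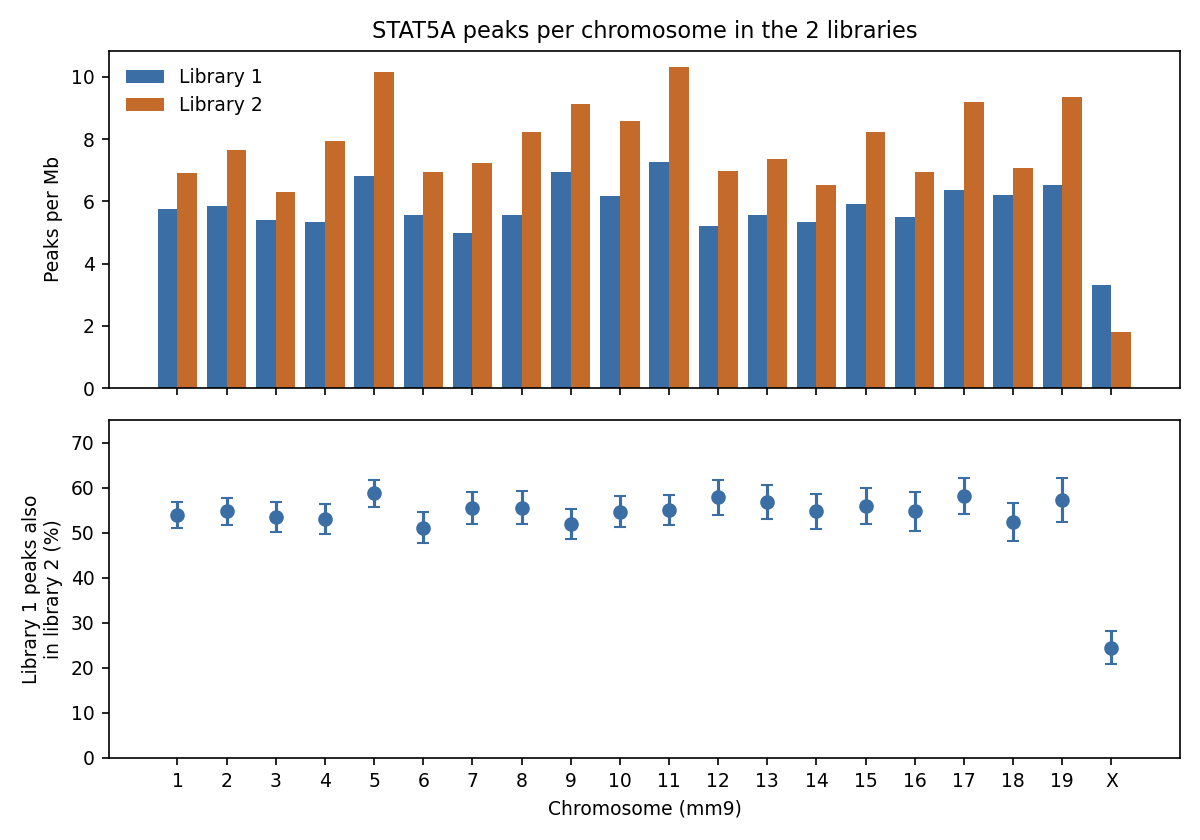
Top, STAT5A peaks per Mb of each chromosome's span of peaks (y axis) by chromosome (x axis) in library 1 and library 2. Bottom, percentage of library 1 peaks also found in library 2, with 95% Wilson intervals, where the autosomes lie between 51.2 and 58.8% and X at 24.4%.

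Shared STAT5A sites lay in clusters more often than random positions on the same chromosomes. There were 60 runs of at least 3 shared sites with neighbours within 20 kb, against a mean of 28.9 in random redraws (permutation test, one-sided p = 0.001, the smallest that the redraws could give). They held 188 shared sites, 2.39% of the total, and 8 of the clusters lay on chromosome 5. That chromosome held 597 shared sites and was among the densest in them, at 4.01 per Mb. No chance number of clusters is given for single chromosomes. The largest cluster had 5 shared sites over 38.9 kb on chromosome 1, from 122370185 to 122409043, where library 1 scores ran from 23 to 59 and library 2 scores from 10 to 18. A cluster of 4 shared sites spanned 16.4 kb on chromosome 7, from 28445105 to 28461465, with scores of 23 to 31 and 10 to 13. Another 4 shared sites spanned 22.1 kb on chromosome 15, from 98960320 to 98982396, with scores of 23 to 35 and 9 to 15, and a further peak of library 2 alone. In total 6 clusters had 4 shared sites and 53 had 3. When positions were redrawn within 500 kb of their own site, a choice made after seeing the data, the chance mean was 48.8 and the excess did not pass the threshold (permutation test, one-sided p = 0.054).

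**Figure D3:**
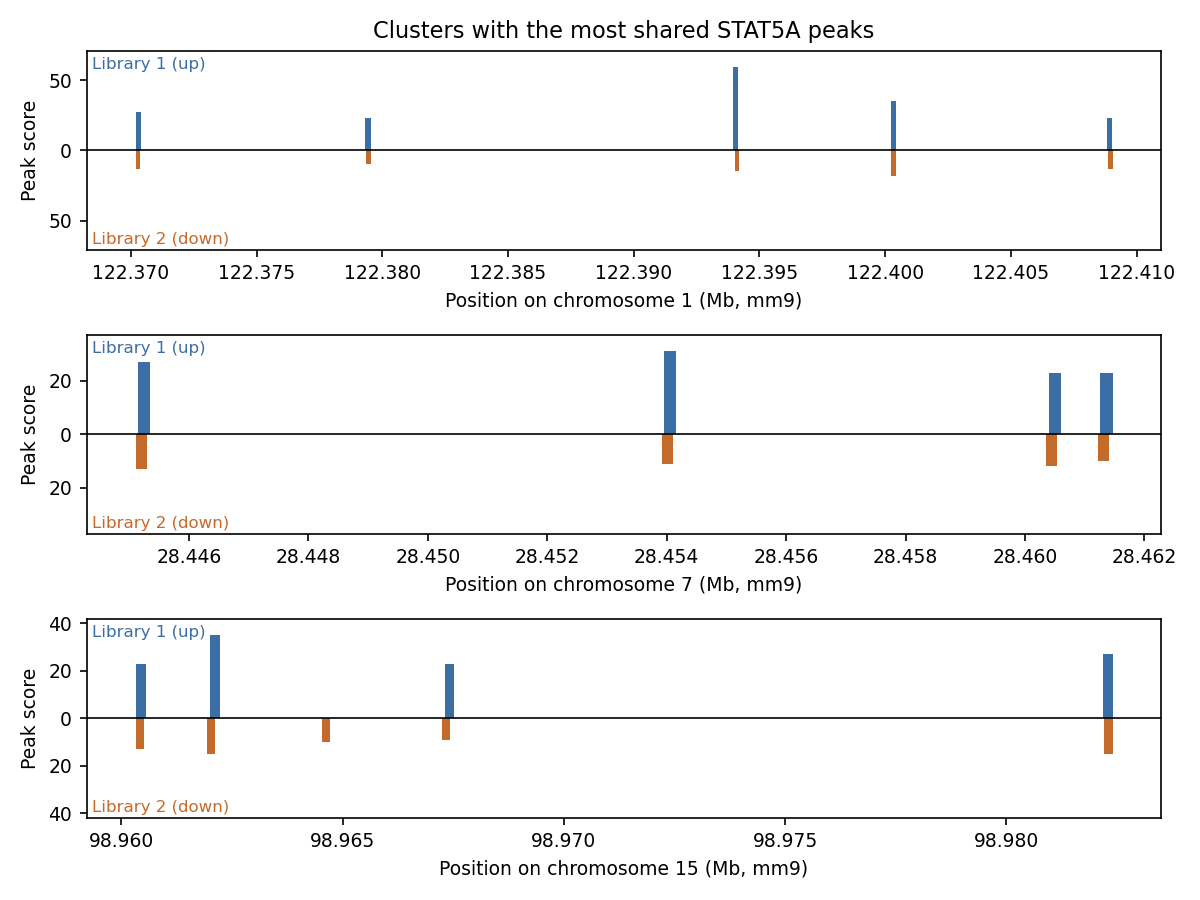
Peaks in the 3 named clusters of shared STAT5A sites by position on mm9 (x axis, Mb) with the deposited score as bar height (y axis), library 1 upwards and library 2 downwards. The clusters hold 5, 4 and 4 shared sites, and 1 peak in the chromosome 15 cluster was found in library 2 alone.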

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

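The excess of shared peaks over chance held its direction and its side of the threshold under all 8 alternatives of overlap rule, score threshold, list length, chromosomes and chance model. The multiple of the chance number was 132 with local shifts, 245 with peaks above the median score, 334 with centres within 100 bp, 50.5 within 500 bp and 352 with overlap of 50% of both widths. The shared fraction of library 1 ranged from 36.8% with only peaks above the median score of each list to 55.0% with autosomes only, and that of library 2 from 28.3% to 44.7%. The lowest value of each counted only partners above the median score, so it is not the shared fraction of higher-scored peaks against the full list. The excess of X peaks in library 1 was 2.97 times with peaks above the median score and 2.38 times without the 50 highest-scored peaks of each list. The rank correlation of scores lay between 0.08 and 0.09 in its 3 alternatives, and the difference in median score between shared and single-library peaks did not move with the overlap rule. The number of clusters depended on its settings by construction, since distance and peak number set it. It was 15 at 10 kb, 255 at 50 kb, and 280 to 790 when all peaks of 1 library were used alone. Each of these was above its chance number. Against positions redrawn within 500 kb the 60 clusters exceeded the chance mean of 48.8 without passing the threshold (permutation p = 0.054). The alternatives for gene position, motifs and gene lists were not run, because no mm9 sequence or annotation was used. No paired analysis was possible because the labels give no replicate numbers and the input had no peak list among the files analysed. The redraw within 500 kb, the clusters of autosomes alone (60, as with all chromosomes), the exclusion of the 50 highest scores and the settings of the score correlation were chosen after seeing the data. With no read totals and no input peaks, sites with low scores cannot be separated from background. Shared sites are not told apart from background common to both libraries either, and a site missing from 1 list is not shown to be unbound.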

Other observations

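The tests of explanations for the X and Y peaks, of the highest-scored peaks, of the score values and of the ratio of the libraries against gene content were chosen after their results were seen, as were the gene content relations of each library alone and the neighbour test of library 2. The comparison of peak shares between chromosomes, the relation of gene content to shared peaks and the neighbour tests of library 1 were set before. Over the 19 autosomes, library 2 had more STAT5A peaks per Mb where protein-coding genes were denser (Spearman's rho 0.70, permutation p = 0.0012, adjusted p = 0.0046 over 4 relations; Pearson's r 0.62, p = 0.0047, adjusted p = 0.012, and 0.73 with p = 0.0011 without chromosomes 7 and 11). Library 1 peaks and shared peaks did not pass the test, with rho of 0.37 (adjusted p = 0.16; r 0.41, p = 0.08) and 0.33 (adjusted p = 0.17; r 0.45, p = 0.053). Without chromosomes 7 and 11, the farthest from the median gene content, r was 0.58 (permutation p = 0.015) for library 1 and 0.61 (permutation p = 0.0097) for shared peaks, so whether Pearson's r passes for them rests on those chromosomes. The rank correlation was not repeated without them. Among the autosomes, chromosome 11 had the most peaks per Mb in both libraries, 7.28 in library 1 and 10.3 in library 2. The ratio of the autosome's share in library 2 to that in library 1 also rose with gene content (rho 0.66, p = 0.0025, adjusted p = 0.005; r 0.60, p = 0.0062, adjusted p = 0.012, and 0.59 with p = 0.013 without the same chromosomes), from 0.87 on chromosome 18 to 1.13 on chromosome 5. A candidate explanation is that library 2 favoured gene-rich or GC-rich sequence. Base composition was not tested.

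Peaks found in 1 library only showed a small tendency to lie near peaks of the other. Of 6750 such peaks in library 1, 16.0% had a library 2 peak within 10 kb, against 13.1% after circular shifts, a ratio of 1.22 (permutation test by shifting, one-sided p = 0.001), which was below the ratio of 1.5 set in advance as evidence of binding at neighbouring sites. After shifts of 200 kb to 1 Mb the ratio was 1.05 (permutation p = 0.05). Its range of 0.99 to 1.11 comes from the spread of the shifted counts and is not a confidence interval of the observed share. The ratios for library 2 were 1.31 and 1.07 (permutation p = 0.001 and p = 0.007). Most of the excess may therefore come from regions of generally higher peak density rather than from clusters of nearby sites.

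The X and Y differences are the result most in need of a second look. A depth or threshold effect alike on all chromosomes would give X and autosomal peaks equal odds of recovery at the same library 1 score. At the same score, the odds of finding an X peak in library 2 were 0.25 times those of an autosomal peak (95% interval 0.21 to 0.31). Equal score need not mean an equal share of background peaks, since library 1 had 3.31 peaks per Mb on X against an autosomal median of 5.74. The control of peak calling is also unknown, so the test cannot set depth or threshold aside. Removal of X regions from the library 1 list would lower the number of X peaks there. Library 1 instead held more of them, 537 against 294, with an X share 2.40 times as high. The share alone would not decide, since removal of autosomal regions would raise it. Whether regions were removed from the library 2 list is not known. A single X copy in the cells of library 2, with more in library 1, stays open. If scores were proportional to copy number, a halved copy number would shift the log2 ratio of library 2 to library 1 scores by -1 relative to autosomes. Whether STAT5A scores on X follow copy number was not tested, so this value is no firm yardstick. The median shift was -0.241 (bootstrap 95% interval -0.266 to -0.141, permutation p = 3e-05), but only the 131 X sites that passed the library 2 threshold could be measured. For the 39 Y peaks of library 2, removal of Y sequence from the library 1 list stays open too. That list kept 3 Y peaks, so the chromosome was not removed whole. The labels give no sex for the donors, and the design named no biological group to test.

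The highest-scored peaks were mostly unshared, as in the highest score classes above. Of the 50 highest of library 2, 2 were found in library 1. Of these 50 peaks, 21 lay within 200 kb of the first peak on an autosome, against 47 of the other 19186 peaks. The peak with the highest score, 267, was among the 21, on chromosome 11 at 3093051 to 3093239. The window starts at the first peak of either list, and 17 of the 21 were not themselves that peak. The 21 lay close together on 6 autosomes and are not independent, so no p-value is given. Assembled mouse chromosomes begin next to the centromere, so repeats near centromeres that were removed from the library 1 list but kept in that of library 2 are a possible explanation for these 21. The test cannot tell, because that explanation called for no library 1 peak in these windows. Library 1 had 16 peaks in such windows over its whole list, and how many lay in the windows of the 21 is not given here. Removal from the library 1 list does not account for library 1 peaks that were unshared. Of its 50 highest, 16 were found in library 2, 0 lay at a chromosome start and 7 lay on X.

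The scores take few distinct values, 32 in library 1 and 73 in library 2. Every score could be written as a whole number times a constant, cut to a whole number, with a constant just under 4.00 in library 1 and of 1.16 in library 2. None of 1000 random sets of as many values in the same range could be so written with a constant as large, in either library. The scores may thus be tag numbers scaled by library. The median peak would then hold 7 tags in library 1 (95% Poisson interval 2.81 to 14.4) and 10 in library 2 (4.80 to 18.4), and the constants differ 3.45 times. If both lists were scaled to the same total, which no source states, library 2 would have been the deeper library by that factor.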
